A study of Homo sapiens with 24 samples.

How the data were processed

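Gene expression was measured in HEK cells, an established human embryonic kidney line, in a design that crosses a DNA minor groove binding ligand with ionizing radiation. Per the labels, cells were plated 24 h beforehand and left untreated, given 50 µM of the ligand, given 2 Gy of radiation, or given the ligand 1 h ahead of the radiation. They were harvested 4 h after treatment. Per the labels' protocols, RNA was extracted with TriReagent, cleaned on RNeasy columns, amplified by T7 transcription from an oligo(dT) primer and labelled with Cy3. Each of the 4 groups had 3 numbered replicates. Each replicate was hybridized to 2 one-colour arrays, called set A and set B here, which gave 24 arrays in all. The ligand is not named in the labels and is called the ligand throughout.

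The deposited array files give a single Cy3 intensity per probe on a linear scale, per the file headers and values. Each set carries 19700 human probes, and 0 probes occur on both sets. The scanner and its software are not given in the sources used here. No foreground or background columns were present in the tables used. The low intensities of the empty spots look as if a background had been subtracted already, but no header or label states this. On up to 35 probes of an array the intensity exceeded 65535, the limit of a 16-bit scan, so some rescaling took place that no source used here describes. The files of replicate numbers 1 and 2 also list empty spots, Arabidopsis control spots and human control spots. Those of number 3 list human probes only. The authors' deposited series matrix holds log2 values. Set against the intensities of each array, its ranks were identical (Spearman 1), and its value distributions were equal between replicates only when sets A and B of a replicate were joined into a single column. The mean absolute difference of sorted values was then at most 0.0019, against up to 0.998 for set A alone. The authors' log2 values thus had 1 common distribution over the joined sets, as judged from the values. Their direction was that of intensity, without centring of probes. Joining alone does not account for numbers 1 and 2. In number 1 the matrix medians differed between the sets by 0.484 in every group, and in number 2 by 0.501 to 0.505. In the deposited log2 intensities these gaps ran from 0.348 to 0.654 and from 0.254 to 0.484. What made the gaps equal there is not stated in the sources used here. Their medians per array ranged in set A from 7.69 to 8.55 and in set B from 8.05 to 8.93.

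Here the linear intensities were taken to log2 and quantile normalized over the 12 arrays of each set apart. Probes that were listed as not detected on some array, be it a single one, were removed, 33 in set A and 87 in set B, which left 39280 probes. Control and empty spots were left out of normalization and tests. Per set, limma 3.58.1 in R 4.3.3 fitted group means (lmFit, contrasts.fit and eBayes). For each of 6 comparisons the Benjamini-Hochberg adjustment ran over the probes of both sets, with a threshold of 0.05 on the adjusted p. Tests were two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

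The design, the groups, the alternatives and the rule for named probes were fixed before the data were examined. The alternatives were median scaling in place of quantile normalization, the authors' series matrix values, removal of the dimmest 25% of probes, the replicate number as a block, array weights, an intensity trend with a robust prior, a fit of the compared groups alone, the file format as a block, an added requirement of a 2-fold change, and each replicate of each group left out in turn. A background correction with normexp was planned and needs columns that the tables used do not have.

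Replicate numbers are shared between groups in the labels, which do not say what a number marks. In each array set the deviations of samples from their group means were correlated between groups for samples of the same number. All 36 such pairs correlated above 0.1, the lowest at 0.200. The numbers were therefore taken to pair the samples, on the evidence of the data and not of the labels, and values with the replicate block are given beside the main ones where they differ by more than 1.5 times. Pairs of different number and group reached up to 0.394. The lowest pairs of numbers 1 and 3 lay above that, at 0.506 and 0.693, but the lowest of number 2, 0.200, did not. For number 2 the pairing, and with it the block and the exchanges within numbers, is therefore less well founded. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

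The files identify probes only by the array maker's numbers, and 0 of these matched the gene table at hand. Genes are therefore not named, and the 28 gene lists and the panel of 28 genes fixed beforehand could not be tested. The rule for named probes asked for a mean intensity outside the lowest 25% of the set, no overlap between the 3 values of each group, and an adjusted p below 0.05. Where too few passed, probes with the smallest unadjusted p were taken and given as values that did not pass. Since probes could not be named, at most 2 that were higher and 2 that were lower are identified. One of the latter, B#27718, was chosen after its values were seen, because an alternative called it. It takes the place of a set B probe that the rule gave as lower after radiation.

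The fit was tested on simulated data in which 39280 probes kept their means per replicate number and received normal noise with their own residual SD after the block. For ligand against untreated, 0 of 100 probes changed by 1 on the log2 scale were called, and 26 of 100 changed by 2, with 0 false calls. With the replicate block 27 and 77 of 100 were called, with 7 false calls. Of the unchanged probes, 0.773% had an unadjusted p below 0.05 without the block and 4.99% with it. For radiation against untreated the fit called 0 and 30 of 100, and with the block 32 and 72 of 100, again with 7 false calls. The simulated noise was independent between arrays, and so lacked the gap, described below, between unirradiated and irradiated arrays of number 2. The simulated rates therefore need not hold for the real data. With the block, 0.985% of real probes had an unadjusted p below 0.05 for ligand against untreated, below the simulated 4.99%. The number of arrays limits the precision: the median half-width of the 95% confidence interval of a log2 difference between groups was 0.82, and 0.49 with the replicate block. The correlation of ligand effects was tested with an exact test that exchanges treated and control samples within numbers, and correlations of control spots with 100000 permutations over all 8 arrays and with all 576 exchanges within numbers.

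A slow trend of intensity along the print layout was seen in some arrays. As an added alternative, each array's deviation from the mean array was smoothed with a running median over 51 neighbouring probes, in the row order shared by the files of numbers 1 and 2, and subtracted. A probe was held to be above the empty spots when it exceeded their 95th percentile on that array, which the files of numbers 1 and 2 allow. For a probe below it, a fold is given as a bound from the lowest normalized signal above that percentile on each such array, with fitted differences beside it where all replicates were used.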

Results

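HEK cells were left untreated, exposed to the ligand, irradiated, or irradiated after the ligand, with 3 replicates per group and 39280 human probes tested over array sets A and B. A DNA minor groove binding ligand lies in the shallow groove of the double helix, and the series asks how such a compound modifies the response to radiation. The median probe intensity per array ranged from 34.5 (radiation, replicate 3, set A) to 677 (untreated, replicate 1, set A), with a median of 323 over the 24 arrays. Radiation replicate 3 stood apart in set A only, since its set B array had a median of 213. In replicate number 2 the irradiated arrays were dimmer than the unirradiated ones. Set A medians were 250 for radiation and 248 for ligand plus radiation, against 654 for untreated and 582 for ligand.

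**Figure D1:**
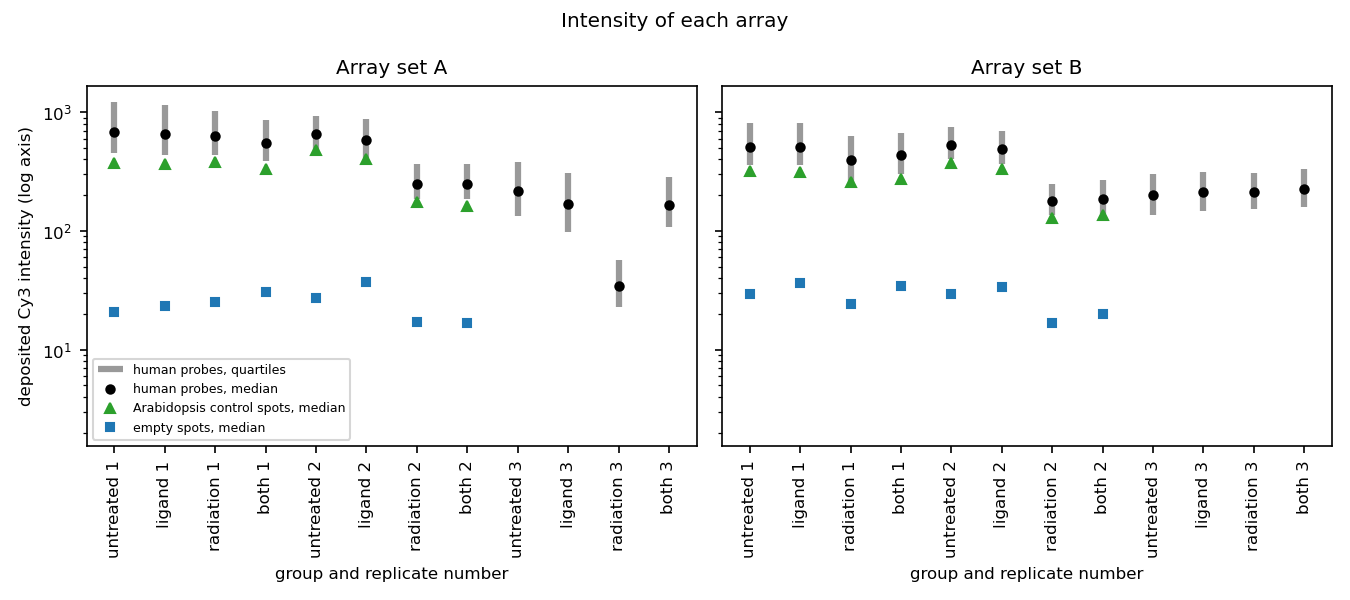
Deposited Cy3 intensity of each array on a log axis, with the median (black points) and quartiles (grey bars) of the human probes, and the medians of Arabidopsis control spots (green triangles) and empty spots (blue squares) where the files list them. "Both" stands for ligand plus radiation, and the human medians run from 34.5 to 677.

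The arrays grouped by replicate number and not by treatment. Over both sets, normalized log2 values of samples with the same number and different treatment correlated at a mean r of 0.859 across probes, against 0.628 for samples of the same treatment and different number. Of the 24 arrays, 23 had their closest partner within their own number. Replicate number took 62.9% of the variance in set A and 62.5% in set B. Ligand took 2.52% and 3.36%, radiation 6.89% and 6.0%, and their interaction 2.51% and 3.93%. Relative to the residual left after number and treatment, the mean square of ligand was 0.602 in set A and 0.833 in set B, that of radiation 1.64 and 1.49, and that of the interaction 0.599 and 0.973. Number 2 was itself divided. Its untreated and ligand arrays correlated at a mean r of 0.931 with each other and at 0.699 with its irradiated arrays. With the arrays of number 1 the irradiated ones correlated at 0.837 and the unirradiated ones at 0.694.

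**Figure D2:**
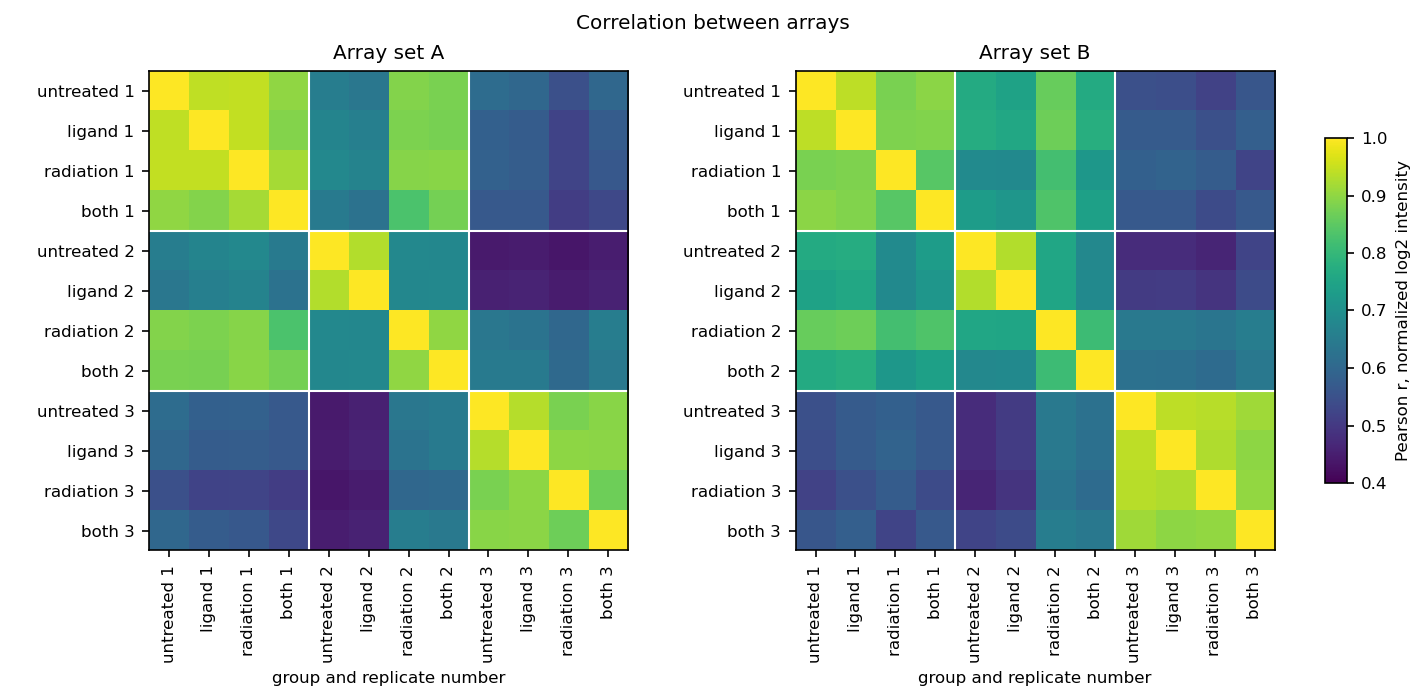
Pearson correlation across probes between the 12 arrays of set A (left) and of set B (right), ordered by replicate number with white lines between numbers; "both" stands for ligand plus radiation. Squares of high correlation follow the replicate numbers, and in number 2 the unirradiated and irradiated pairs separate (mean r 0.699 between them).

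Ligand against untreated asks what the ligand alone does to expression in unirradiated cells. No probe passed the limma test (0 of 39280 at an adjusted p below 0.05), and 44 had an unadjusted p below 0.05, of which 13 were higher and 31 lower with ligand. These are 0.112% of probes, against 0.773% of unchanged probes in simulated data with paired numbers. Median scaling gave 8 higher and 40 lower. With the replicate block, 0 passed and 387 had an unadjusted p below 0.05, 193 higher and 194 lower. The blocked fit of the compared groups alone, chosen after seeing the data, gave 0 and 1634, so these counts depend on the residual used. Among lower values the rule for named probes gave probe A#17739. Its mean normalized log2 intensity was 6.72 ± 1.56 (SD, n = 3) with ligand and 9.08 ± 0.48 (SD, n = 3) without. The fitted difference was −2.37 (SE 0.69, limma adjusted p = 1.0). In ligand replicate 1 the probe was no brighter than the 95th percentile of the empty spots, so it was at least 14.1-fold lower in number 1 and at least 4.93-fold lower in the mean, as bounds. In numbers 2 and 3 the differences were −2.95 and −0.14, so 2 of the 3 numbers carried it. Probe B#39351 was higher in all 3 numbers, by 0.51, 1.37 and 0.19, with a mean difference of 0.69 (SE 0.24, limma adjusted p = 1.0). The 3 ligand values and the 3 untreated values did not overlap for 1.34% of probes. Chance gives 10% for samples that are not paired, but exchanging treatments within numbers gave 1.05% to 1.34%. The ligand differences of separate numbers were nearly uncorrelated across probes in set A, at r of 0.042, 0.042 and 0.012.

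Radiation against untreated asks what 2 Gy does by 4 h. In limma 0 probes passed, and 303 had an unadjusted p below 0.05, 103 higher and 200 lower. In the authors' series matrix the balance was the opposite, with 360 higher and 206 lower. The probe picked as higher, A#39082, had a mean log2 intensity of 9.65 ± 0.30 (SD, n = 3) after radiation and 8.26 ± 0.25 (SD, n = 3) in untreated cells. The difference was 1.39 (SE 0.30, limma adjusted p = 1.0, and 0.777 with the replicate block), and it was positive in all 3 numbers at 1.93, 1.43 and 0.82. In the deposited intensities it was higher in number 1 only. The values of the groups did not overlap for 3.52% of probes, against 10% by chance for unpaired samples and 2.66% to 3.21% when treatments were exchanged within numbers. The replicate block left 0 probes past the threshold and 2334 at an unadjusted p below 0.05, 1063 higher and 1271 lower. Of these 2334, 1745 lay on set B, which is 8.90% of its probes, and 589 on set A, which is 2.99%. After the trend along the print layout was removed, an alternative chosen after seeing the data, the blocked count on set B was 919 and that on set A 738.

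Ligand plus radiation against untreated compares the combined treatment with no treatment. Again 0 probes passed in limma, and 205 had an unadjusted p below 0.05, 115 higher and 90 lower, a balance that turned to 43 and 54 when dim probes were left out. Blocked by replicate number, the fit gave 0 and 1610 probes at an unadjusted p below 0.05, 766 higher and 844 lower. Probe B#27718 had a mean log2 intensity of 6.49 ± 2.06 (SD, n = 3) after both treatments and 8.60 ± 0.32 (SD, n = 3) in untreated cells, a fitted difference of −2.11 (SE 0.75, limma adjusted p = 1.0). Its deposited intensities of 23.4 and 29.0 in replicates 1 and 2 were below the 95th percentile of the empty spots, so the fitted difference is not a measured size. In replicate 3 the difference was −0.13. Without ligand plus radiation replicate 3 it was the only probe called (limma adjusted p = 0.00964). Set against the lowest signal above that percentile, it was then at least 3.82-fold lower, and the call rests on values not above the empty spots. Probe A#39082 had a difference of −0.41 (SE 0.30), below 0 in all 3 numbers.

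Ligand plus radiation against radiation asks what the ligand adds in irradiated cells. In limma 0 probes passed, and 397 had an unadjusted p below 0.05, 213 higher and 184 lower with ligand. In the authors' series matrix there were 123 higher and 303 lower. Probe A#39082, which had the higher values after radiation alone, was lower by −1.80 (SE 0.30, limma adjusted p = 1.0). The rule picked it for high values on these same radiation arrays, so the choice alone favours a difference below 0. Its differences by number were −2.18, −2.23 and −0.99. Its adjusted p was 0.724 with the replicate block. With arrays weighted by their quality it was called (−2.22, SE 0.16, limma adjusted p = 0.00101). Probe B#27718, not above the empty spots in replicates 1 and 2 of the combined treatment, did not pass (limma adjusted p = 1.0) and was 0.33 higher in replicate 3. Without that replicate it was called (limma adjusted p = 0.0135), at least 3.51-fold lower by the same bound. With the replicate block, 0 probes passed and 2655 had an unadjusted p below 0.05, 1362 higher and 1293 lower, with 1991 of the 2655 on set B. After removal of the layout trend the set B count was 707.

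**Figure D3:**
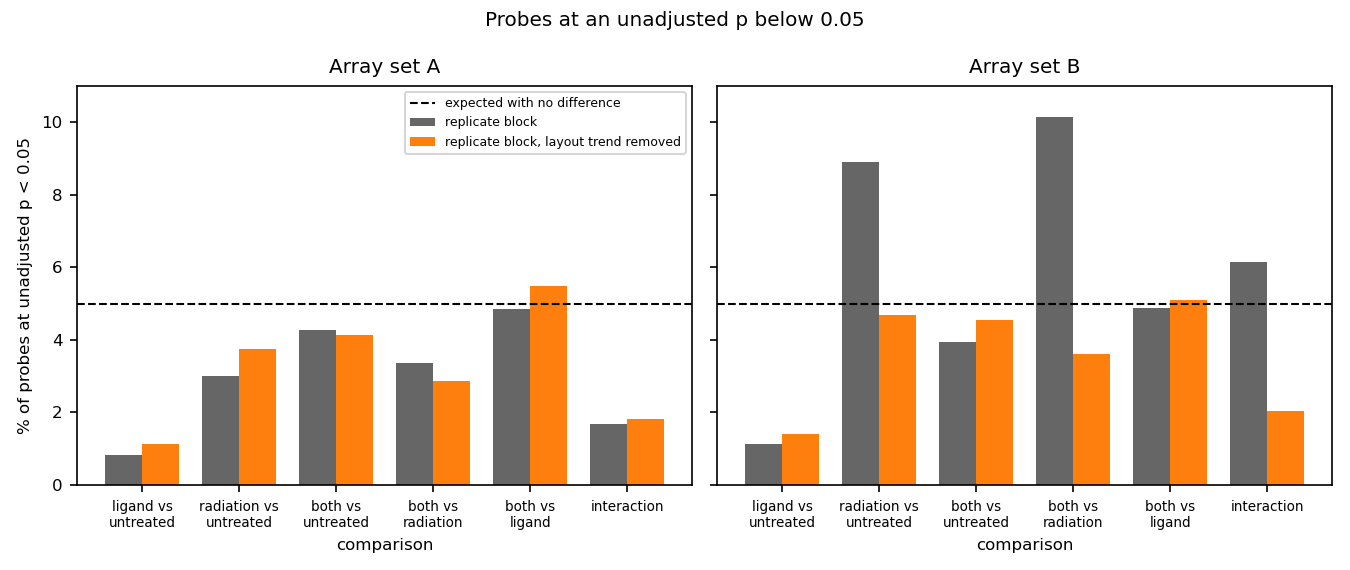
Share of probes with an unadjusted limma p below 0.05 in each comparison, for set A (left) and set B (right). Bars are from the fit with the replicate block, before (grey) and after (orange) the trend along the print layout was removed. "Both" stands for ligand plus radiation. The dashed line marks the 5% that no difference would give with independent noise, a level from which exchanges within numbers departed. On set B radiation against untreated falls from 8.90% to 4.69%, and ligand plus radiation against radiation from 10.2% to 3.60%.

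Ligand plus radiation against ligand asks what radiation does in cells that had the ligand. There were 0 probes past the threshold in limma and 209 at an unadjusted p below 0.05, 125 higher and 84 lower, and median scaling gave 146 higher and 157 lower. The replicate block gave 0 and 1910, of which 846 were higher and 1064 lower. The radiation-associated difference of probe A#39082 was −0.17 here (SE 0.30, limma adjusted p = 1.0), with values of −0.04, −0.64 and 0.17 by number. Probe B#27718 did not pass (limma adjusted p = 1.0) and was 0.24 higher in replicate 3. Without ligand plus radiation replicate 3 it was called (limma adjusted p = 0.00896), at least 3.89-fold lower as a bound, again from values not above the empty spots.

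The interaction asks whether the ligand's effect differs between irradiated and unirradiated cells. In limma 0 probes passed and 187 had an unadjusted p below 0.05, 137 above 0 and 50 below. This balance reversed in the authors' series matrix, with 32 above and 113 below, and was even after the layout trend was removed in the blocked fit, with 379 each way. With the replicate block 0 passed and 1537 had an unadjusted p below 0.05, 850 above 0 and 687 below. Probe A#39082 had an interaction of −1.56 (SE 0.42, limma adjusted p = 1.0, and 0.971 with the block), with values of −1.97, −2.07 and −0.65 by number. These values contain the radiation difference for which the probe was picked, so the choice favours their sign. The median half-width of the unadjusted 95% interval of an interaction was 1.15 on the log2 scale, or 0.69 with the block. Smaller interactions were not resolved for a typical probe. Larger ones can be missed too, since the threshold was adjusted over 39280 probes.

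Across all probes, the ligand's differences in unirradiated and in irradiated cells, which share no arrays, correlated at Pearson r = −0.042 and Spearman rho = −0.065. Probes are not independent replicates. Exchange of treated and control samples within numbers gave a two-sided exact p of 0.375 for r and 0.25 for rho, where the smallest possible was 0.0625. By replicate number, r was −0.089, 0.034 and −0.067. The corresponding correlation of the radiation difference without and with ligand was 0.055 in number 1, 0.670 in number 2 and 0.031 in number 3.

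Comparisons that share the untreated arrays correlate by construction. The simulated groups had noise independent between arrays, with each probe's residual SD after the block. They lacked the gap within number 2, so the simulated levels need not hold for the real data. Ligand alone and radiation alone correlated at r = 0.322, against 0.499 in simulated unchanged groups, with a covariance of 0.0264 against 0.0562. Ligand alone and ligand plus radiation gave r = 0.276 (simulated 0.502), with a covariance of 0.0232 against 0.0567. Radiation alone and ligand plus radiation gave r = 0.570 (simulated 0.50), with a covariance of 0.0727 against 0.0563. Without number 2 the latter pair fell below the simulated level, at r = 0.313 and a covariance of 0.0345 against 0.0560. The 3 untreated replicates were not split between the compared differences, so part of each value may come from the shared controls.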

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

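The tests in this part were chosen after the results they bear on had been seen. Signal appeared in spots outside the comparisons: Arabidopsis control spots were 10.8 times as bright as empty spots in the median of the 16 arrays that list them, and no array lay below 6.76. Whether Arabidopsis RNA was added is not stated in the sources used here. Of the 10 human control sequences, 9 had a mean level above every one of the 13 Arabidopsis control sequences. With the ligand, probe B#39351 was higher in all 3 numbers of unirradiated cells, while in irradiated cells its mean difference was −0.29 (SE 0.24, limma adjusted p = 1.0). After the layout trend was removed the latter was −0.07, with number 2 at 0.08, so a fall in irradiated cells is not established. The difference between these effects was −0.99 (SE 0.35, limma adjusted p = 1.0), and −0.76 after that removal. Both values contain the rise in unirradiated cells for which the probe was picked, so the choice favours a value below 0.

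The unirradiated and irradiated arrays of number 2 stood apart, in both array sets. A fault of single arrays would leave sets A and B unrelated, since they were separate hybridizations. Over the 10 human control sequences the gap on set A correlated with that on set B at r = 0.987, with 10 of 10 of the same sign and the largest at −3.01 and −2.47 log2, which argues against it. The gaps of the 13 Arabidopsis sequences were smaller (SD 0.193 against 1.63 on set A), with r = 0.717 and 6 of 13 of the same sign. That r leans on 1 sequence, with gaps of 0.566 on set A and 0.357 on set B. The largest of the others in size were −0.205 on set A and −0.233 on set B. A trend along the layout is argued against too, because the mean correlation between these arrays was 0.714 after its removal, against 0.937 for untreated with ligand. Radiation acting alike on every number is argued against by the highest correlation of the number 2 difference with another number, 0.113. With the unirradiated arrays of numbers 1 and 3, the unirradiated arrays of number 2 correlated at a mean of 0.590 and its irradiated arrays at 0.743. The irradiated ones were higher in 4 of 4 combinations of set and number, without overlap in 3, and in 4 after the layout trend was removed (means 0.657 and 0.807). If the numbers had started alike, a response to radiation in number 2 alone would give the opposite order. Since the numbers differ for reasons not known, it stays open, as does a difference of culture, RNA or labelling.

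On set B an excess of small p-values appeared with the replicate block in the comparisons that hold the radiation group. There were 1745 probes for radiation against untreated, 1991 for ligand plus radiation against radiation and 1206 for the interaction. Independent noise would give 980.6, but exchanges within numbers, given below for both sets, departed from such a level. A trend along the print layout is a candidate explanation. Differences of neighbouring probes correlated at up to 0.544 in layout order for radiation replicate 1 against untreated. After the trend was removed the counts were 919, 707 and 400, each below 980.6. On set A the first of them went from 589 to 738. Since 980.6 need not hold for these data, how much of the excess the trend explains stays open. A radiation effect on particular genes of set B stays untested, since the probes have no names.

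In the authors' series matrix, radiation against untreated had 684 probes at least 2-fold lower and 97 higher on set A, but 50 lower and 453 higher on set B. With the sets normalized apart the numbers were 214 and 305 on set A, and 128 and 141 on set B. Joint normalization of sets A and B is a candidate explanation: number 3 shifted in the matrix by a median of −0.809 on set A and 0.829 on set B. With the sets apart the shifts were 0.026 and 0.0074. Those carry no weight, since quantile normalization of each set gives its arrays 1 common distribution and so keeps such shifts near 0. The largest such shift in numbers 1 and 2 was 0.0855, which cannot decide on radiation acting on the cells. There the matrix held the medians of each set nearly equal between groups, in number 1 at 8.53 on set A and 8.05 on set B. In the deposited log2 medians of number 1 the gap between the sets ran from 0.348 to 0.654. Shifts were thus kept near 0 there, and radiation as a cause stays open. The dim set A array of radiation replicate 3, whose log2 median was 5.11 against 7.73 on set B, is the array concerned.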

How the results depend on the processing

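The layout trend, number 2 left out, the Arabidopsis filter and the fit of compared groups with the block were chosen after seeing the data, and the other settings before. The count of probes past the threshold was 0 in each of the 6 comparisons. It was 0 under every setting run for ligand against untreated (26 settings), radiation against untreated (26) and the interaction (24). Among these, the added requirement of a 2-fold change could only give 0, since it filters the main fit. The replicate block gave 0 in all 6 and changed no call. For ligand plus radiation against radiation the array weights gave 1, probe A#39082, and the weights did not fully converge. Leaving out single replicates gave 0 to 1 against untreated, against radiation and against ligand, in each case B#27718 without ligand plus radiation replicate 3, where its differences were −0.13, 0.33 and 0.24. Its other values after both treatments were not above the empty spots. The cause of the call under array weights was not tested. The ligand effect correlation was −0.042. It moved to −0.154 in the series matrix and to 0.022 with array weights, the cause not tested, and ranged from −0.070 to 0.015 over left-out replicates, of which those without untreated 2, radiation 3, and ligand plus radiation 1 and 2 moved it by more than its spread. With the block it stayed at −0.042, as it must.

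The 4 probes taken by the rule kept their direction under every setting run. Leaving out replicates could hardly turn it, since the rule asked for groups without overlap, and the block leaves the difference unchanged. The probe that is not identified, lower after radiation, went from −0.87 to −0.41 when the layout trend was removed. Counts at an unadjusted p below 0.05 and their balance of directions moved widely: 14 to 1634 for ligand against untreated, 128 to 2334 for radiation, 96 to 2444 for both against untreated, 202 to 3558 against radiation, 94 to 2209 against ligand and 89 to 2019 for the interaction. With number 2 left out and the block, 0 probes passed in all 6 comparisons, as with the 8086 probes above the Arabidopsis level. The normexp background correction and the gene list tests were not run. The median human probe was 1.52 times the median Arabidopsis spot, and whether those spots measure background is not known.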

Other observations

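The tests in this part were chosen after the results had been seen, apart from the comparisons themselves. Probe A#39082 had the pattern of a transcript raised by radiation and not raised when the ligand came first. It was picked for high values on the radiation arrays, which also enter its difference from the combined treatment, so the choice favours this pattern. Its mean log2 intensity was 8.26 in untreated cells, 8.02 with ligand, 9.65 after radiation and 7.85 after both (n = 3 each, SD 0.25, 0.20, 0.30 and 0.47). Its deposited intensity after radiation was 2165 against 566 in untreated cells in number 1, but 554 against 641 in number 2 and 73.0 against 272 in number 3. On set A, where the probe lies, the radiation arrays of numbers 2 and 3 were dimmer as a whole than the untreated ones. The rise there exists only after normalization. The radiation array of number 3 was low and coarsely stepped, with quartiles of 23 and 56.5. With 39280 probes tested and an adjusted p of 1.0 for the interaction, it is a single probe to look at again and no more.

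Probes A#17739 and B#27718 had another pattern, low values in numbers 1 and 2 of one group only. On set B the deposited intensity of B#27718 was 23.4 and 29.0 in ligand plus radiation replicates 1 and 2, where the empty spots had medians of 34.5 and 20.03, and 329 in replicate 3. In the other groups it ranged from 191 to 702. A#17739 stood at 63.0 and 162 in ligand replicates 1 and 2, against 1677 and 1150 in untreated cells. Probes no brighter than the 95th percentile of the empty spots numbered 50 to 754 on the 8 arrays of set B that list such spots, and 19 to 152 on those of set A. The highest count in each set was that of ligand plus radiation replicate 1. On set B replicate 2 of that group had 190, and 79 were shared by the 2 arrays, against 7.27 expected for independent lists. Ligand replicate 1 and ligand plus radiation replicate 1 shared 152 against 12.9 expected. Every pair of these set B arrays shared more than expected, with 22 against 0.129 for untreated replicates 1 and 2. Such an overlap is therefore not particular to the combined treatment. On set A, where A#17739 lies, there were 47 in ligand replicate 1 and 52 in replicate 2, with 4 on both against 0.124 expected. Arrays of different groups overlapped there too, such as ligand replicate 2 and radiation replicate 1 with 10 against 0.203, so this is not particular to the ligand group.

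The 10 human control sequences occur on both array sets and so measure each labelled sample on separate hybridizations. Their deviations from the mean over 8 arrays correlated between sets at r = 0.931 (permutation p = 2e-05, two-sided, 100000 permutations). Those of the 13 Arabidopsis sequences did so at r = 0.715 (permutation p = 3e-05), so the agreement is not particular to the human controls. These permutations ignore the replicate numbers. The 100000 draws are more than the distinct orders of 8 arrays, so orders recur and both permutation p-values are approximate. With deviations taken within numbers and all 576 exchanges within them, r was 0.919 for the human sequences (exact p = 0.00174, the smallest possible). For the Arabidopsis sequences r was 0.527 (exact p = 0.00347).

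A median of 26.9% of human probes (range 12.2% to 37.4% over 16 arrays) lay above the 95th percentile of the Arabidopsis spots.

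A change of at least 2-fold in the same direction in all 3 numbers was seen for 2 probes with ligand against untreated, 2 with radiation, 5 with both, 7 with ligand plus radiation against radiation and 11 against ligand. Turning the sign of one number round gave means of 0.667, 6.67, 6.67, 2 and 13. After the layout trend was removed these counts were 2, 2, 4, 0 and 9, against means of 1, 2.33, 3.33, 1 and 4.

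With the replicate block, exchanging the groups within numbers gives 4 arrangements, too few to exclude chance. The real arrangement gave 387 probes at an unadjusted p below 0.05 for ligand against untreated, where the highest of the others gave 372. For radiation these were 2334 and 2117, for both against untreated 1610 and 2854, for both against radiation 2655 and 1782, and for both against ligand 1910 and 3111. After the layout trend was removed the order turned in 3 of the 5: radiation gave 1657 and 2110, both against untreated 1705 and 1651, and both against ligand 2078 and 1862. The remaining ones were 495 and 457 for ligand, and 1272 and 1175 for both against radiation.

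Other splits of the samples were counted in the limma fit without the block. The real count was 0 in each comparison, so every split had to give as many, and the counts of splits carry no information on chance: 10 of 10 for each of the 5 pairwise comparisons, where the highest of the other splits was 0, and 100 of 100 drawn for the interaction. Among the latter the highest called 9499 probes, which points to a structure of the samples other than the treatments.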
